A study of Mus musculus with 8 samples.

How the data were processed

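Total RNA from finely ground hippocampus of male C57BL/6J mice, 11 weeks old, was profiled on 1 slide of SurePrint G3 Mouse GE 8x60K oligonucleotide arrays, which carries 8 arrays. Per the labels, 4 groups were studied with 8 mice each: sedentary mice on a placebo diet (SED), mice given mild treadmill exercise on the placebo diet (ME), sedentary mice on an astaxanthin diet (AX), and mice given both (AX+ME). The diet powder made up 0.5% of the food, and 2% of the powder was astaxanthin. Each group has 2 samples, replicate 1 labelled with Cy3 and replicate 2 with Cy5, each alone on its array. How the RNA of 8 mice became 2 samples is not stated. Nothing says that the 2 samples of a group come from separate animals, so every p-value measures a spread between samples that may be technical.

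Per the labels' protocols, RNA was isolated with an RNeasy Mini kit and labelled with a Low Input Quick Amp two-colour kit. The deposited scanner files hold spot intensities from Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes. Per the file headers, a 2-channel extraction protocol was run with spatial and multiplicative detrending, and the probe design refers to mouse genome build mm9. The processed signal is a linear intensity, background-subtracted and detrended within the array, and not scaled between arrays. The deposited series-wide value list holds the same intensities rounded to whole numbers: every value lay within 0.5 of the own-channel processed signal, so its direction and linear scale are known and it is not centred or scaled. Its medians were 121, 139, 159 and 177 for the Cy3 samples of SED, ME, AX and AX+ME, and 178, 202, 212 and 193 for the Cy5 samples.

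The processed signal of the channel that held the sample's RNA was used. Control spots (3671 per array) and spots marked as non-uniform were left out, and saturated spots were kept. Of 59305 other spots, spots of the same probe were averaged, giving 55681 probes, of which 26582 had a gene symbol through the reference gene table or the files and 29099 had none. Signals were divided by the array's 75th percentile over all probes that are not controls and put on a log2 scale. A probe was kept where it was well above background on both arrays of at least 1 group (37415 probes), and of several probes of a gene the brightest over all 8 samples was used. This left 27171 genes and unnamed transcripts, 16076 of them with a symbol. Symbols were assigned by accession, and no coordinates were used.

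All 8 samples entered a single limma model with a term for each group and a term for dye, with empirical Bayes moderation (3 residual degrees of freedom, 1.57 prior degrees of freedom). The tested differences were ME against SED, AX against SED, AX+ME against SED, AX+ME against ME, AX+ME against AX, the interaction (AX+ME minus ME minus AX plus SED), and the 2 main effects: exercise averaged over diets and astaxanthin averaged over activity. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Each group has 1 sample per dye, so a difference was also computed within each dye. Genes at least 1.5-fold apart the same way in both dyes were counted beside those 1.5-fold apart in opposite ways. Noise symmetric about 0 and independent between dyes would give equal numbers of both. A shift shared by dim genes, or a filter that keeps genes for being high in a group, breaks that symmetry. The slide's row is the dye and its column is the group, so position on the slide and group cannot be told apart.

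For 37 lists of pathway genes and of marker genes of cell types or tissues, limma's camera was run with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The correlation was then estimated from the residuals, and fry was run on each list alone. With the estimate, camera's test has at most the 3 residual degrees of freedom, so not passing is weak evidence against a list. The median log2 difference is given for each list. The named genes are, for each comparison, the 10 largest differences up and the 10 largest down among genes past the threshold that moved the same way in both dyes. Where fewer passed, the next places went to genes with the smallest unadjusted p that were at least 1.5-fold apart the same way in both dyes, given as values that did not pass. Leptin (Lep), its receptor (Lepr) and at most 4 list members past the threshold, over all genes or over the list alone, were named as well, and unnamed transcripts were passed over. These rules, the lists, the model and most alternatives were fixed before the data were examined.

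A gene well above background on neither array of a group has only a bound there. It is given as "at least N-fold": the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Both groups' measured means stand beside it in the result tables. This value holds only for these samples and this processing. It includes no error between samples, and under other settings the difference could be smaller.

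After maps of the arrays had been seen, the model was also fitted to the 17770 genes and transcripts with a probe in array columns from 70 on, using only spots there. A probe counts as in the columns below 70 where at least as many of its spots lie below as from 70 on. Other settings chosen after seeing the data were that fit with quantile normalization, the 6 samples without SED, leaving out population outlier spots, the median over a probe's spots, and normexp background correction on the median signal because the files hold no mean signal. Alternatives chosen before were quantile normalization, median scaling, the series value list, no filter on dim probes, a filter on all 8 arrays, every probe tested on its own, a prior variance with a robust trend, no dye term, saturated probes left out, only the 4 samples compared, 2-level models for the main effects, fold thresholds of 1.2 and 2, and leaving out each sample in turn. Loess normalization within arrays was not run, since the other channel of every array is empty.

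The fit was tested on simulated data for AX+ME against ME, with 27171 genes, 20 simulated sets and 200 changed genes in each. It recovered 7.99% of genes changed 1.5-fold, 52.9% of those changed 2-fold and 82.9% of those changed 4-fold, with 4.30% false among the calls. A list of 15 genes shifted by 0.40 on the log2 scale passed the list test in 100% of sets and an unshifted list in 0%. The simulated genes varied independently of each other, and no simulated array had a dim area. These rates therefore say nothing of lists whose genes vary together. For comparisons that share the SED samples, unchanged groups were simulated 20 times against them. Computations used R 4.3.3, limma 3.58.1, jsonlite 2.0.0 and the data.table package in version 1.17.8, and figures used Python 3.11.15 and matplotlib 3.10.9.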

Results

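Expression of 27171 genes and unnamed transcripts was measured in the hippocampus, the brain region for spatial memory and adult neurogenesis, of mice in 4 groups with 2 samples each. The groups cross mild treadmill running (ME) with a diet holding astaxanthin (AX), a red carotenoid antioxidant from an alga, against sedentary mice on placebo (SED). The series title asks whether leptin made in the hippocampus carries the gain in neurogenesis and memory when the treatments are combined (AX+ME). Of 59305 spots per array, 71.6%, 72.7%, 76.2% and 71.5% were well above background in the Cy3 samples of SED, ME, AX and AX+ME, and 65.0%, 64.0%, 63.2% and 66.9% in the Cy5 samples. The 75th percentile of the signal was 1420, 1652, 1775 and 1964 in the Cy3 samples and 2045, 2319, 2319 and 2081 in the Cy5 samples. Between 919 and 1474 spots were saturated. Correlations between arrays lay between 0.986 and 0.998, across genes. The number of arrays, 2 per group, limits the precision.

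Both SED arrays carried swirl-shaped areas of dim spots over array columns below 70, and none of the other 6 arrays did. Of 678 probes at least 0.8 log2 lower in SED than in the other groups in both dyes, 666 (98.2%) lay there, against 41.8% of all probes kept. The same count was 27 probes for ME, 8 for AX and 27 for AX+ME. The dim spots were a minority: the median log2 difference of all probes in these columns from the other arrays of the dye was 0.02 in SED replicate 1 and 0.03 in SED replicate 2. Against SED, the limma totals and the counts at 1.5-fold in both dyes are therefore given also for the 17770 genes with a probe from column 70 on. In that fit, limma called 0, 0 and 3 genes for ME, AX and AX+ME against SED and 0 for the other comparisons. Unadjusted p-values under 0.05 were then held by 3562, 4072 and 5406 genes against SED, and by 2416 for AX+ME against ME and 1727 for AX+ME against AX. Log2 differences of genes named from those columns moved little. For ME against SED, Trh went from -1.62 (SE 0.0880, adjusted p = 0.00973) to -1.57 (SE 0.0845, adjusted p = 0.0769). The adjusted p rose although the SE did not, since fewer genes with very small p-values were left to share the adjustment. Calls over all columns against SED were lost or nearly lost with any ME, AX or AX+ME sample left out. This held also for comparisons that do not use the sample left out. The calls were most numerous without SED replicate 1. Each of these fits has fewer residual degrees of freedom and leaves a group with 1 sample. These changes therefore do not show that a comparison rests on the sample left out.

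**Figure D1:**
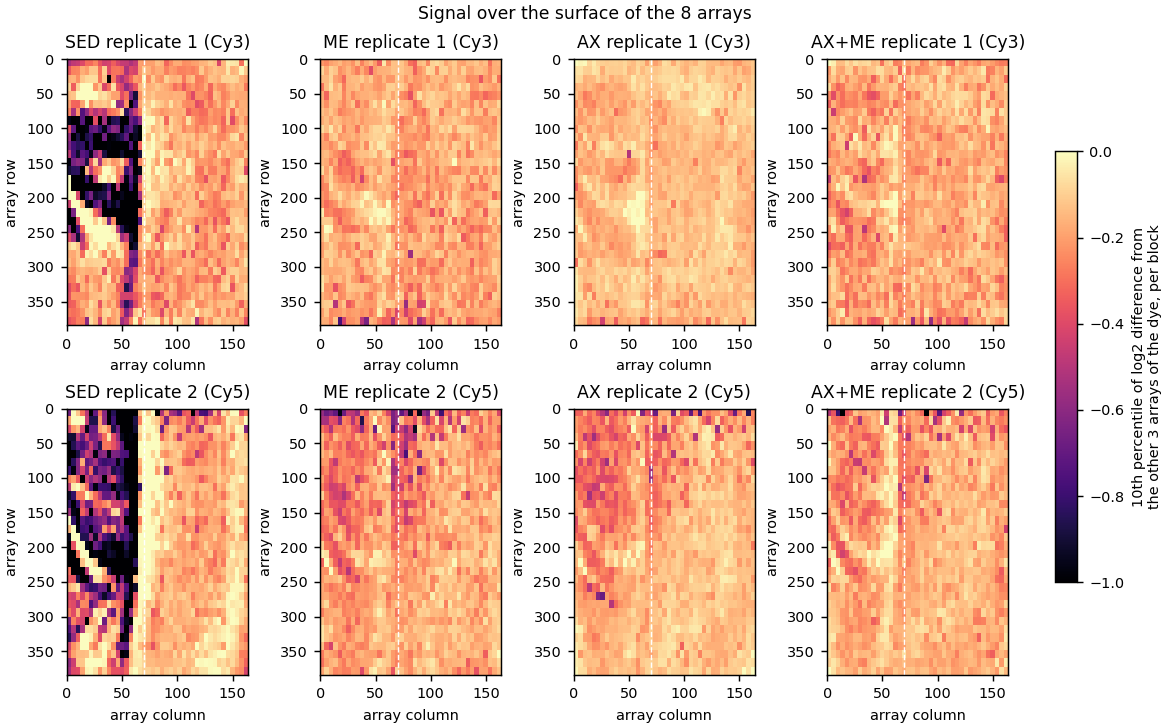
Each panel is 1 array by column and row, coloured by the 10th percentile, per block of spots, of the log2 difference from the other 3 arrays of the same dye (dark is dimmer); the dashed line marks column 70. Dark swirls appear left of the line on both SED arrays, where 666 of the 678 probes lower in SED in both dyes lie.

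Mild running alone, ME against SED, went with lower Prl, Gh, Trh and Pomc, genes of pituitary and hypothalamic hormones. By camera, genes of the choroid plexus, the tissue that makes cerebrospinal fluid, were lower as a group, and so were genes of meningeal fibroblasts, which make the collagen of the brain's coverings. Neither list passed with an estimated correlation between genes (adjusted p = 0.335 and adjusted p = 0.756). Lists of neurogenesis, synaptic plasticity and leptin signalling did not pass. The hypothalamus list, which holds Trh, had a median of -0.26 with 7 of 10 genes lower and did not pass (adjusted p = 0.676). Nearly all genes that were higher after running had their probe in the dim part of the SED arrays.

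Prl, which encodes the pituitary hormone prolactin, fell by 2.77 on the log2 scale in ME (SE 0.192, adjusted p = 0.0128). It was not well above background on either ME array, so that the drop is given as at least 5.28-fold. Over 22 other settings the log2 difference of Prl ranged from -3.07 to -1.31. Trh, the precursor of thyrotropin-releasing hormone, fell by 1.62 (SE 0.0880, adjusted p = 0.00973). Gh, growth hormone, fell by 1.62 as well, with a wider SE of 0.234 (adjusted p = 0.0483) and a signal well above background on only 1 of the 2 ME arrays, and Pomc, the precursor of corticotropin and endorphin, fell by 1.12 (SE 0.0598, adjusted p = 0.00973). The chemokine gene Ccl7 fell by 1.11, at least 1.41-fold, and Prg4, which encodes the joint lubricant lubricin, fell by 1.01. All 6 were lower in both dyes and lie outside the dim columns. Oit3 (at least 1.77-fold), H2-Aa, Vash1 and Six2 fell by 1.64, 1.12, 1.03 and 0.96 with probes in those columns. Another probe of Vash1, outside them, gave 0.11. The 10 largest rises all had probes in the dim columns, from Sdhaf3 at 1.95 to Fbxw13 at 2.90; among them were Olfr1349 (2.60; at least 4.20-fold), Zfp872 (2.42), Abhd3 (2.39; at least 3.80-fold), Nsrp1 (2.30), Zfp324 (2.18), Htra4 (2.05), Trp53bp2 (2.04) and Ssxb8 (2.01; at least 2.91-fold). Outside them, Isl1, a transcription factor of striatal and motor neurons, rose by 1.17 (adjusted p = 0.0154, at least 2.14-fold). In the fit from column 70 limma called 0 genes for ME against SED (smallest adjusted p = 0.0769).

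All 16 choroid plexus genes were lower in ME, with a median log2 difference of -0.44 (camera adjusted p = 6.27e-07, and adjusted p = 0.335 with an estimated correlation). Of these, 7 passed over all genes and 13 adjusted over the list alone. The coagulation factor gene F5 fell by 0.64, the water channel gene Aqp1 by 0.76 with a probe in the dim columns, the potassium channel subunit gene Kcne2 by 0.51 and the transcription factor gene Otx2 by 0.50. Of 10 meningeal fibroblast genes, 9 were lower, with a median of -0.40 (camera adjusted p = 0.0175, and adjusted p = 0.756 with an estimated correlation); 2 passed over all genes, the collagens Col3a1 (-0.84) and Col1a2 (-0.47), and 6 adjusted over the list alone. The pituitary list, of which 5 genes could be tested, had a median of -1.12 and did not pass (adjusted p = 0.0556); from column 70 it did, with a median of -1.57 over 3 genes (adjusted p = 4.78e-05, and adjusted p = 0.244 with an estimated correlation). The lists tied to the study's title did not pass: the median was -0.13 for neural stem and progenitor cells (adjusted p = 0.672), -0.07 for immature neurons (adjusted p = 0.848), -0.17 for proliferation (adjusted p = 0.660), 0.01 for synaptic plasticity (adjusted p = 0.794) and -0.12 for leptin signalling (adjusted p = 0.672). The median over all tested genes was -0.05.

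In the limma test 530 genes were higher and 277 lower in ME, with 6505 at an unadjusted p under 0.05. Of the higher genes 98.1% had their probe in the dim columns and of the lower genes 56.0%, where 42.0% of tested genes lie. At 1.5-fold in both dyes, 728 genes were higher, 204 lower and 136 went opposite ways. From column 70 these counts were 26, 90 and 24.

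Astaxanthin in sedentary mice, AX against SED, also went with lower Trh. The dopamine receptor gene Drd1 and the early response genes Egr1 and Egr2, which neurons switch on when active, were modestly lower. Lcn2, an iron-binding protein of inflammation and stress, and Oxt, the hormone oxytocin, were higher. None of these genes passed in the fit from column 70. No list passed camera, while fry, which tests a list against no change, passed 10 of 37.

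Trh fell by 1.92 (SE 0.0880, adjusted p = 0.0103) in AX, in both dyes. Lce1i, a gene of the skin's outer layer, fell by 1.099 (adjusted p = 0.0163), and both lie outside the dim columns. The other 8 of the 10 largest falls had probes in them. H2-Ob, an immune gene, fell by 1.75, while another of its probes, outside the dim columns, gave -0.25. Oit3 fell by 1.64 (at least 1.84-fold). For Utp6, Ndrg4 and Rpl35, saturated in both groups, no fold is given. The 10 largest rises all had probes in the dim columns, with Fbxw13 (2.66), Zfp872 (2.65), Abhd3 (2.47; at least 4.02-fold), Olfr1349 (2.33; at least 3.49-fold) and Nsrp1 (2.17) in front. List members outside these columns that passed over all genes were Oxt (0.84, adjusted p = 0.0247), Lcn2 (0.65, adjusted p = 0.0188), Egr2 (-0.50, adjusted p = 0.0495), Egr1 (-0.34, adjusted p = 0.0441), Drd1 (-0.65, adjusted p = 0.0188), Pomc (-0.60, adjusted p = 0.0239), Col3a1 (-0.58, adjusted p = 0.0326) and Socs3, an inhibitor of leptin signalling (-0.35, adjusted p = 0.0469). None of them passed in the limma fit from column 70, which called 0 genes for AX against SED (smallest adjusted p = 0.0956).

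In limma 598 genes were higher and 516 lower in AX, with 7429 at an unadjusted p under 0.05. Probes in the dim columns made up 94.98% of the higher and 60.5% of the lower genes. At 1.5-fold in both dyes 780 were higher, 234 lower and 134 opposite, and from column 70 these were 48, 51 and 31. The smallest adjusted p of any list was 0.182, shared by mitochondrial respiration (median -0.15), proliferation (-0.19) and pericytes and smooth muscle (0.14). For leptin signalling the median was -0.13 (adjusted p = 0.329).

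The combined treatment, AX+ME against SED, went with lower choroid plexus genes by camera, as running alone did, but not with an estimated correlation (adjusted p = 0.326). Trh was lower again. Differences of prolactin and growth hormone from SED did not pass, and growth hormone was higher in both dyes. Among the largest rises were receptors of the nose that hippocampus is not known for, with signals close to background. The lists for neurogenesis, plasticity and leptin signalling did not pass.

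Outside the dim columns, the olfactory receptor gene Olfr661 rose by 2.38 (adjusted p = 0.0171; at least 3.35-fold) and the pheromone receptor gene V1ra8 by 2.12 (adjusted p = 0.0307; at least 3.52-fold). The falls outside them were Rax, a transcription factor of hypothalamus and retina (-1.69, adjusted p = 0.0353), Trh (-1.31, adjusted p = 0.0110) and Sox14, a transcription factor of interneurons (-0.995, adjusted p = 0.0417; at least 1.53-fold). Fbxw13 (3.36), Zfp872, Olfr1349, Abhd3, Olfr122, Tm4sf19, Htra4 and Nsrp1 were the other large rises and Oit3, H2-Ob, Vash1, Utp6, Ndrg4 and Rpl35 were among the other falls, all with probes in the dim columns. List members outside them included Egr2 (-0.62, adjusted p = 0.0307), Egr1 (-0.32, adjusted p = 0.0398), Klf4, a transcription factor of the same early response (-0.47, adjusted p = 0.0327), Pomc (-0.71, adjusted p = 0.0157) and Slc4a1, the anion exchanger of red blood cells (0.76, adjusted p = 0.0290). Prl differed by -0.03 (adjusted p = 0.935) and Gh by 0.64 (adjusted p = 0.143).

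All 16 choroid plexus genes were lower in AX+ME than in SED, with a median of -0.51 (camera adjusted p = 4.60e-07, and adjusted p = 0.326 with an estimated correlation); 11 passed over all genes and 13 adjusted over the list alone. Kcne2 fell by 0.70, F5 by 0.65, Steap1, a metal reductase gene, by 0.62 and Ecrg4, which encodes a secreted peptide precursor, by 0.68. No other list passed. The medians were -0.14 for neural stem and progenitor cells (adjusted p = 0.507), 0.01 for immature neurons (adjusted p = 0.992), -0.18 for proliferation (adjusted p = 0.269) and -0.15 for leptin signalling (adjusted p = 0.339). In limma 1048 genes were higher and 1093 lower, with 8848 at an unadjusted p under 0.05. Probes in the dim columns made up 76.4% of the higher and 55.7% of the lower genes. At 1.5-fold in both dyes 1039 were higher, 311 lower and 153 opposite, and from column 70 these were 247, 64 and 29. The 3 genes called in the fit from column 70 were Olfr1232 (1.63, adjusted p = 0.0288), the keratin gene Krt80 (1.06, adjusted p = 0.0347) and an unnamed transcript, named after their values were seen.

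**Figure D2:**
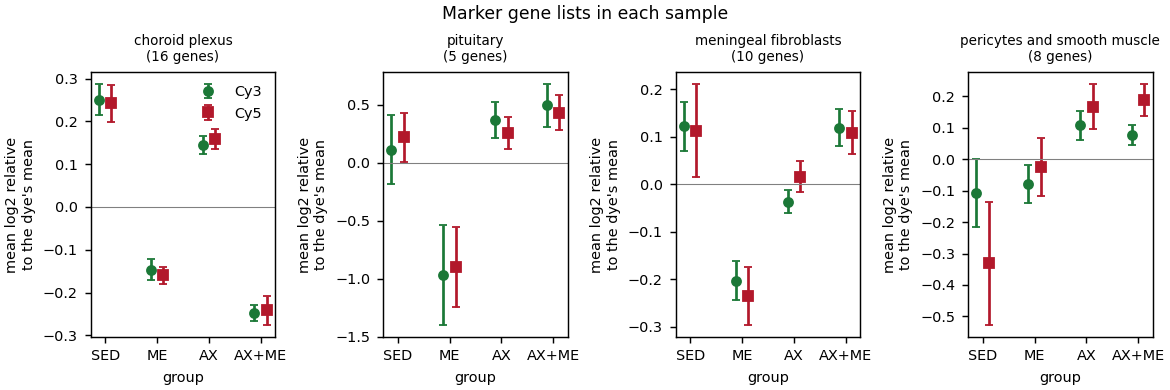
Points are the mean log2 signal over a list's genes in each sample, relative to the mean of the 4 samples of its dye, with bars of the standard error over genes, by group and dye. Choroid plexus genes lie at 0.25 and 0.24 in SED and 0.14 and 0.16 in AX, against -0.15 and -0.16 in ME and -0.25 and -0.24 in AX+ME.

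The 3 comparisons against SED share its 2 samples and so share chance values. Their log2 differences correlated across genes at 0.797 (ME and AX), 0.793 (ME and AX+ME) and 0.794 (AX and AX+ME), where unchanged groups simulated against the same samples gave 0.502, 0.498 and 0.495. From column 70 the correlations were 0.549, 0.591 and 0.597 beside simulated ones of 0.500, 0.494 and 0.512. The covariances were 0.108, 0.116 and 0.118 beside simulated ones of 0.0192, 0.0189 and 0.0188, and from column 70 they were 0.0352, 0.0418 and 0.0440 beside 0.0136, 0.0133 and 0.0140. All 3 comparisons called 488 genes higher, 485 of them in the dim columns, and 155 lower, 108 of them there. ME and AX shared 489 higher and 177 lower genes, where independent lists of these sizes would share 11.7 and 5.26. For ME and AX+ME the shared calls were 521 and 210 beside 20.4 and 11.1, and for AX and AX+ME 570 and 436 beside 23.1 and 20.8. With the difference of each comparison taken from the other dye, so that no SED sample is shared, the correlations were 0.319, 0.333 and 0.344, and from column 70 they were 0.154, 0.199 and 0.211.

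Adding astaxanthin to running, AX+ME against ME, changed no single gene past the threshold. By camera the pituitary, meningeal and vessel wall lists were higher than with running alone, and the early response genes of active neurons slightly lower. None of these lists passed with an estimated correlation (adjusted p = 0.243 to adjusted p = 0.248). These comparisons leave the SED arrays out of the difference, though not out of the estimate of spread.

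No gene passed in limma (0 genes, 2242 at an unadjusted p under 0.05; smallest adjusted p = 0.158). Without passing, the smallest p-values among genes higher at least 1.5-fold in both dyes were those of Krt80 (1.08, adjusted p = 0.158), the embryonic globin gene Hbb-bh1 (1.11, adjusted p = 0.161), Cst10, a protease inhibitor gene (1.04), Prl (2.74, adjusted p = 0.167; at least 5.19-fold), Olfr910 (1.38; at least 1.48-fold), Olfr1232 (0.85), the mast cell protease gene Mcpt4 (0.67) and H2-Q1 (0.73). Lower without passing were Mael, a germ line gene (-1.91, adjusted p = 0.304; at least 2.02-fold), Xlr4b (-1.05), Vpreb2 (-0.98) and Prdm12 (-0.77). All 5 pituitary genes were higher, with a median of 1.30 (camera adjusted p = 7.89e-08, and adjusted p = 0.243 with an estimated correlation), and 4 passed adjusted over the list alone. For meningeal fibroblasts 9 of 10 genes were higher, with a median of 0.36 (camera adjusted p = 7.34e-06, and adjusted p = 0.243 with an estimated correlation), and 5 passed adjusted over the list alone. Of 8 genes of pericytes and smooth muscle 7 were higher, with a median of 0.11 (camera adjusted p = 0.00105, and adjusted p = 0.248 with an estimated correlation). Of 23 immediate early genes 20 were lower, with a median of -0.10 (camera adjusted p = 0.00107, and adjusted p = 0.248 with an estimated correlation). Choroid plexus genes were lower by a median of -0.09 (camera adjusted p = 0.00750, and adjusted p = 0.287 with an estimated correlation). That list did not pass with quantile normalization. Striatal genes were higher by 0.12 (camera adjusted p = 0.0276, and adjusted p = 0.539 with an estimated correlation). The striatal list did not pass from column 70. The brightest 10% of all genes were lower as well, by a median of -0.06. In both dyes 256 genes were at least 1.5-fold higher and 35 lower, with 48 opposite. With quantile normalization within each dye 134 were higher and 72 lower. With probes above background on all 8 arrays 53 were higher, 4 lower and 8 opposite, and with normexp 8, 3 and 4. The dimmest 10% of genes had a median of 0.16, so the opposite count is not a fair measure of noise here.

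Adding running to astaxanthin, AX+ME against AX, went with lower choroid plexus genes by camera once more, with lower genes of the ciliated ependyma that lines the ventricles and with slightly higher striatal marker genes. None of these passed with an estimated correlation (adjusted p = 0.0611, adjusted p = 0.351 and adjusted p = 0.351). No single gene passed the threshold.

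Limma called 0 genes (1648 at an unadjusted p under 0.05; smallest adjusted p = 0.337). Higher without passing, taken by smallest p among genes 1.5-fold apart in both dyes, were Olfr1232 (1.00, adjusted p = 0.337), Cst10 (0.97), Krt80 (0.70), Olfr910 (1.21), Olfr661 (2.01), the thyroid transcription factor gene Foxe1 (1.13), Olfr1339 (0.92), Olfr166 (0.87) and Hbb-bh1 (0.64). Lower without passing were the opsin gene Rrh (-0.66, adjusted p = 0.371), Zc3hav1, an antiviral gene (-0.77), Pon1, an esterase gene (-1.01), Klhl31 (-0.76), Sox14 (-0.76; at least 1.3-fold), Wfdc16 (-2.98; at least 5.14-fold) and Scgb3a1 (-1.25), the last with its probe in the dim columns. Of 16 choroid plexus genes 15 were lower, with a median of -0.42 (camera adjusted p = 1.15e-22, and adjusted p = 0.0611 with an estimated correlation), and 12 passed adjusted over the list alone. Ttr, the exception, was saturated on 8 arrays. All 7 ependymal genes were lower (median -0.21, camera adjusted p = 0.000219, and adjusted p = 0.351 with an estimated correlation), and all 11 striatal genes were higher (median 0.22, camera adjusted p = 3.87e-05, and adjusted p = 0.351 with an estimated correlation). Meningeal fibroblast genes were higher (0.11, camera adjusted p = 0.0154), and lower were genes of the glucocorticoid response (-0.04, camera adjusted p = 0.00907), of erythrocytes (-0.15, camera adjusted p = 0.0209) and of dentate granule cells (-0.11, camera adjusted p = 0.0341). With an estimated correlation the adjusted p = 0.351 for the first 3 of these and the adjusted p = 0.506 for dentate granule cells. The erythrocyte list did not pass from column 70 (adjusted p = 0.998). In both dyes 171 genes were at least 1.5-fold higher and 66 lower, with 35 opposite.

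The interaction asks whether running acted differently on the astaxanthin diet than on placebo. Trh was lower in ME, AX and AX+ME than in SED, and least so in AX+ME. On the log2 scale it was -1.45 and -1.73 in the SED samples and between -2.89 and -3.66 in the others. These falls and the positive interaction of Trh rest on the same SED samples. Genes of meningeal fibroblasts and of the pituitary had a positive interaction by camera, and neither list passed with an estimated correlation (adjusted p = 0.765 for both). All 129 genes that passed with a negative interaction had their probe in the dim columns of the SED arrays.

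The interaction of Trh was 2.23 (SE 0.125, adjusted p = 0.0406). Others outside the dim columns were Lce1i (1.59), Hbb-bh1 (1.39), Ptger3, a prostaglandin receptor gene (1.34), the signalling gene Wnt6 (1.32), Cst10 (1.101), Col3a1 (1.09) and Ccl7, of no known size as it was not above background in ME, with adjusted p-values from 0.0412 to 0.0484. Pomc had an interaction of 1.00 (adjusted p = 0.0456) and Drd1 of 0.83 (adjusted p = 0.0483). For Prl, not above background in ME, it lay above 0 and did not pass (adjusted p = 0.0543). Limma gave 30 genes above and 129 below 0 (3972 at an unadjusted p under 0.05), and 100% of the latter but 16.7% of the former had probes in the dim columns. From column 70 the count was 0, with any ME, AX or AX+ME sample left out it was 0, and without SED replicate 1 it was 2822. Meningeal fibroblast genes had a median interaction of 0.50 (camera adjusted p = 0.00370, and adjusted p = 0.765 with an estimated correlation) and pituitary genes of 1.30 (camera adjusted p = 0.0140, and adjusted p = 0.765 with an estimated correlation). At 1.5-fold in both dyes 378 genes lay above, 723 below and 250 opposite, and from column 70 these were 246, 60 and 87.

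Averaged over both diets, exercise went with lower prolactin and Pomc, and by camera with lower choroid plexus genes, which did not pass with an estimated correlation (adjusted p = 0.151). The prolactin and Pomc averages rest on the placebo diet, since Prl differed by -0.16 and Pomc by -0.12 between AX+ME and AX. Averaged over activity, astaxanthin went with higher prolactin and lower Trh, but neither in sedentary and running mice alike: Prl differed by only 0.13 between AX and SED, and Trh was 0.31 higher in AX+ME than in ME, without passing. By camera early response and mitochondrial genes were lower and genes of vessel wall cells higher. None of these lists passed with an estimated correlation (adjusted p = 0.519 to adjusted p = 0.739), and the mitochondrial list passed in only 4 of 14 other settings. The brightest 10% of genes were lower too, by a median of -0.14 in AX against SED and -0.06 in AX+ME against ME. Whether the early response and mitochondrial lists fell beyond such a trend with brightness was not tested.

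For exercise, Prl was lower (adjusted p = 0.0411), with no size given as it was not above background in ME, and Pomc fell by 0.62 (adjusted p = 0.0389), F5 by 0.57 (adjusted p = 0.0389), the protease gene Tmprss11a by 0.54 and the keratin gene Krt23 by 0.52. Outside the dim columns Prdm12, a transcription factor of sensory neurons (0.88, adjusted p = 0.0407), and Olfr1232 (0.85, adjusted p = 0.0389) rose. Limma called 165 genes higher and 36 lower (5229 at an unadjusted p under 0.05), with 93.9% of the higher in the dim columns. From column 70 it called 0 genes for exercise (smallest adjusted p = 0.0879). All 16 choroid plexus genes were lower (median -0.44, camera adjusted p = 3.51e-12, and adjusted p = 0.151 with an estimated correlation); 8 passed over all genes and 13 adjusted over the list alone. For astaxanthin, Prl (adjusted p = 0.0430) and Olfr139 (adjusted p = 0.0422) were higher, with no size given as Prl in ME and Olfr139 in SED were not above background. Oxt rose by 0.74 (adjusted p = 0.0419) and Lcn2 by 0.43 (adjusted p = 0.0422), while Trh fell by 0.81 (adjusted p = 0.0419), Unc13c, a gene of synaptic vesicle release, by 0.63 and Rnf122, a ubiquitin ligase gene, by 0.61. Scarb1, a carotenoid uptake receptor gene, rose by 0.94 on a probe in the dim columns, while another probe outside them gave 0.12 (SE 0.047). Limma called 167 higher and 29 lower (7107 at an unadjusted p under 0.05), with 87.4% of the higher in the dim columns. From column 70 it called 0 genes for astaxanthin (smallest adjusted p = 0.0565). Lists past camera were pericytes and smooth muscle (median 0.23, adjusted p = 0.00842, and adjusted p = 0.519 with an estimated correlation), pituitary (0.65, adjusted p = 0.0152, and adjusted p = 0.519 with an estimated correlation), immediate early genes (-0.12, adjusted p = 0.0223, and adjusted p = 0.519 with an estimated correlation) and mitochondrial respiration (-0.11, adjusted p = 0.0237, and adjusted p = 0.739 with an estimated correlation). The pituitary and mitochondrial lists did not pass from column 70 (adjusted p = 0.201 and adjusted p = 0.824).

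Leptin, the hormone the title names, was close to background on these arrays. Its signal was highest in AX+ME in both dyes, but the difference from SED did not pass the test. The brightest leptin receptor probe was lower in AX and AX+ME, but did not pass with its spot from column 70 on alone.

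Lep has 1 probe (A_52_P374882) with 10 spots on each array, 2 of them in the dim columns. Its mean signals in SED, ME, AX and AX+ME were 25.8, 22.4, 25.8 and 43.2 in Cy3 and 21.7, 37.3, 34.7 and 48.1 in Cy5. The spots well above background numbered 3, 6, 9 and 10 of 10 in Cy3 and 1, 0, 0 and 6 in Cy5. In SED replicate 1 a single spot at 122.7, in the dim columns, raised the mean, and the median over spots was 15.9 there against 43.9 in AX+ME replicate 1; in Cy5 these medians were 24.1 and 46.8. The log2 difference of AX+ME from SED was 0.69 (SE 0.269, adjusted p = 0.161, higher in both dyes; at least 1.29-fold), and with only the spots from column 70 it was 0.96 (SE 0.121, adjusted p = 0.0533). It was 0.09 for ME (adjusted p = 0.865) and 0.08 for AX (adjusted p = 0.878) against SED, 0.60 against ME (adjusted p = 0.637), 0.61 against AX (adjusted p = 0.861) and 0.52 for the interaction (adjusted p = 0.596). Over 22 other settings the difference of AX+ME from SED ranged from 0.04 to 1.14, with adjusted p from 0.0125 to 0.809. It passed in 3, of which leaving out outlier spots (1.08, adjusted p = 0.0278) and the median over spots (0.96, adjusted p = 0.0138) were chosen after the data were seen, and the remaining setting left out SED replicate 1 (1.14, adjusted p = 0.0125). Among these settings Lep passed against SED in ME as well, with the median over spots (0.53) and without SED replicate 1 (0.55), and in AX without SED replicate 1 (0.53). The brightest Lepr probe, with a spot on each side of column 70, fell by 0.51 in AX (adjusted p = 0.0370) and 0.46 in AX+ME (adjusted p = 0.0365), and differed by -0.19 in ME (adjusted p = 0.184). Its spot from column 70 on alone gave -0.24 and -0.22 for AX and AX+ME and 0.02 for ME, and none passed. The dimmer probes outside the dim columns gave -0.35 and -0.62 in ME, -0.38 and -0.17 in AX, and -0.68 (SE 0.147) and -0.09 (SE 0.176) in AX+ME.

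**Figure D3:**
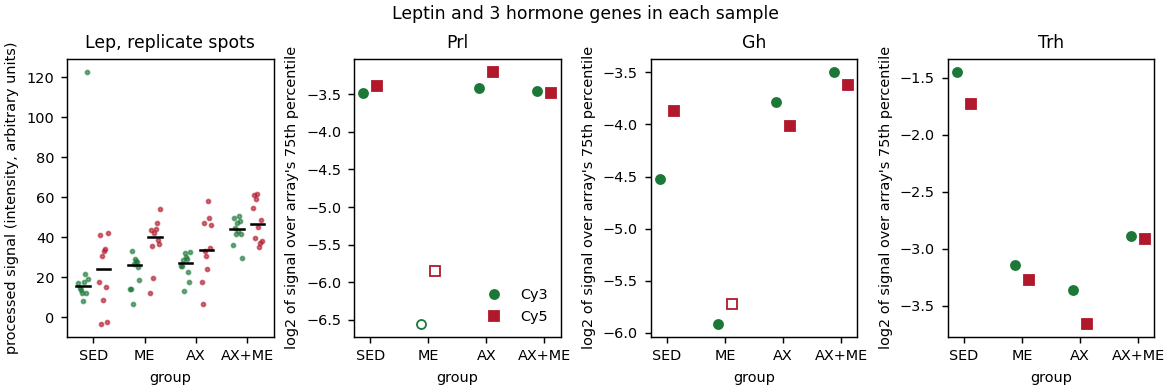
Left, processed signal of the 10 replicate spots of Lep in each sample with bars at the median; right, log2 signal of Prl, Gh and Trh per sample relative to the 75th percentile, with open symbols where the probe was not well above background. Medians of Lep reach 43.9 and 46.8 in AX+ME, and Prl is not above background in ME alone.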

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

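Of the tests below, the comparison of olfactory receptor genes with other dim genes and the rank of leptin among dim genes were chosen before their results were seen; the others were chosen after. What singled out the results was a test of whether exercise acted differently on the 2 diets, or signal in a dye channel that no comparison used.

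The test for an effect of exercise that differs between diets called 159 genes, but 0 from column 70 and 0 with any ME, AX or AX+ME sample left out, and 2822 without SED replicate 1. Above 0, where running lowered a gene less on astaxanthin, raised it more or turned a fall into a rise, were Trh (2.23), Oit3 (1.64), Lce1i (1.59), Ccl7 (1.52), Hbb-bh1 (1.39), Ptger3 (1.34), Wnt6 (1.32), Cst10 (1.101), Col3a1 (1.09), Six2 (1.08), Pomc (1.00) and Drd1 (0.83). Below 0 were Olfr1349 (-2.36), Nsrp1 (-2.35), Abhd3 (-2.34), Cnmd (-2.09), Htra4 (-1.97), Sdhaf3 (-1.94), Palb2 (-1.81), Ska2 (-1.73), Rap1a (-1.71), Arpp19 (-1.65), Cry1 (-1.37), Sox2 (-1.24) and Pdgfrb (-1.002), all with probes in the dim columns of the SED arrays. The sizes for Oit3, Ccl7, Olfr1349, Abhd3, Cnmd and Palb2 are nominal, as each was not above background in at least 1 group. Among lists, meningeal fibroblasts had a median interaction of 0.50 and the pituitary list of 1.30; neither passed with an estimated correlation (adjusted p = 0.765 for both), and without SED replicate 1 the interaction had 0 lists. The dye channel that held no RNA had between 539 and 907 spots marked well above background per array. Its signal rose weakly with that of the used channel (rank correlation across spots 0.168 to 0.234).

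The genes that differed from SED sit mainly where both SED arrays are dim: 98.1% of those higher in ME. For ME against SED, quantile normalization still called 822 genes, 754 of them among the 807 called without it. That comparison had little trend with brightness (median -0.03 in the dimmest 10% of genes, -0.06 in the brightest). The count therefore says little about scaling by brightness. For AX and AX+ME against SED, which had such a trend, calls went from 1114 to 876 and from 2141 to 1565. For the genes called higher in ME in the dim columns, a real change was checked on other probes. Those of 60 genes, outside these columns, had a median log2 difference of -0.012 (SD 0.385), where the called probes had 0.90. This argues against a real change of these genes. Uneven signal over the SED arrays may therefore account for most genes higher in ME, the only comparison tested this way. Of genes higher in AX and AX+ME, 94.98% and 76.4% lay in these columns. Genes lower in ME are less concentrated there (56.0%), and for those elsewhere an effect of running or diet stays open, untested against position on the slide. The array-wide scaling includes the dim columns. Probes from column 70 had medians 0.05 and 0.04 above the dye's other arrays in SED replicates 1 and 2. For ME against SED the median over all genes was -0.046, and 0.0052 in the fit from column 70. In that fit limma called 0 lower genes in ME, AX or AX+ME against SED.

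Choroid plexus genes were lower in both exercised groups, and the pituitary hormone genes Prl and Gh in ME alone. Against a general shift between neurons and other cells, meningeal fibroblast genes were higher in AX+ME than in AX, where choroid plexus genes were lower. The meningeal median was 0.11 (camera adjusted p = 0.0154, and adjusted p = 0.351 with an estimated correlation). Ependymal genes, also not of neurons, were lower there together with choroid plexus genes. In ME against SED the meningeal genes fell with them (-0.40 and -0.44), but 24 genes of astrocytes, oligodendrocytes, their precursors, microglia and endothelium outside the dim columns had a median of -0.0535 (SD 0.134), far from what such a shift needs. Against the dim area as the source for Prl, it was at least 5.19-fold higher in AX+ME than in ME, where it was not above background (measured difference 2.74, in both dyes, adjusted p = 0.167), and this leaves SED out. A differing amount of choroid plexus in the dissected tissue is a possible source of that list's fall. Of its 15 unsaturated genes 100% were lower in AX+ME than in AX. This restates what singled the list out, so it gives no support. A difference in tissue cannot be told apart from an effect of exercise on these genes (median -0.44), which would look alike. Ttr, the list's most abundant transcript, is saturated. For pituitary RNA carried over, only 2 further genes, Pomc and Cga, were lower in ME in both dyes and Lhb was not. Pomc did not follow Prl, since it was lower than SED in AX and AX+ME as well, where Prl hardly differed. With 5 genes tested, carried over RNA cannot be told apart from a change in hormone transcripts.

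Dim genes were higher in AX+ME: against SED the median log2 difference went from 0.15 in the dimmest 10% of genes to -0.13 in the brightest 10%. AX against SED had a like trend, from 0.05 to -0.14, and quantile normalization removes such trends by construction. A dim gene was kept where it was well above background on both arrays of at least 1 group. Such genes are thus partly picked for being high in a group, which for Lep was AX+ME alone. The trend, the olfactory receptor genes and the rank of Lep are all drawn from them. Olfactory receptor genes (217) exceeded other genes of like signal by 0.13 in AX+ME against ME, a size between the bounds set beforehand for a shared effect of brightness and for a separate effect on these genes, so these cannot be told apart. The difference of Lep between AX+ME and SED lay at percentile 66.8 of the 500 genes nearest in signal. Those genes had a median of 0.24, so the rise of Lep may be that of dim genes in general. From column 70 the percentile was 89.0 and the neighbours' median 0.0077, so the neighbours did not rise as a set there. Over all columns, 498 of the 500 neighbours rest on 1 spot, where Lep is a mean of 10. An effect of the combined treatment on leptin stays open, untested.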

How the results depend on the processing

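Settings chosen after the data were seen were normexp on the median signal, array columns from 70 with and without quantile normalization, the 6 samples without SED, leaving out population outlier spots, and the median over spots. The others were chosen before. Unless stated, the cause of a change was not tested.

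Quantile normalization, median scaling, the series table's values, saturated probes left out, population outliers left out and the median over spots kept every total of changed genes within 1.5 times (limma, 0 for AX+ME against ME and against AX in each). Quantile normalization called 822, 876 and 1565 genes for ME, AX and AX+ME against SED, of which 754, 828 and 1443 were among the 807, 1114 and 2141 called without it; lower genes went from 516 to 320 for AX and from 1093 to 717 for AX+ME. For single named genes, 1997 values under these and the other settings with all samples kept direction and side of the threshold, 378 no longer passed, 8 newly passed and 27 changed direction. The kept values include genes that passed in neither fit, such as those named for AX+ME against ME, so they overstate how stable the passing genes were. For lists 92 were kept, 45 no longer passed and 1 changed direction.

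Normexp changed most counts: 1784 (1060 higher, 724 lower) for ME, 4006 (1341 and 2665) for AX and 5596 (1703 and 3893) for AX+ME against SED, 472 (56 and 416) for the interaction, 595 (482 and 113) for exercise and 1058 (544 and 514) for astaxanthin. It moved the median of all genes to -0.14, -0.13 and -0.12 against SED and to 0.14 for the interaction; whether this moved the calls was not tested. Lists past camera became 1 for ME against SED, 1 for the interaction, 2 for exercise and 2 for astaxanthin, and genes 1.5-fold apart in both dyes became 864, 11 and 16 for AX+ME against SED, ME and AX. Lep turned to -0.12 in ME and -0.16 in AX against SED and to -0.00128 for astaxanthin, and Lepr to 0.027 for exercise; none of these passed with or without normexp.

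Without a filter on dim probes limma called 2 genes for AX+ME against ME and 1 for AX+ME against AX, all transcripts without a symbol, with 62 for the interaction and 607 for astaxanthin. With probes above background on all 8 arrays the counts were 1292 for ME and 1858 for AX against SED, 311 for exercise and 387 for astaxanthin; fewer genes were tested, and the counts at 1.5-fold in both dyes were 601, 672 and 797 against SED, 57 and 49 for AX+ME against ME and AX, and 661 for the interaction. Testing every probe gave 71 for the interaction and 99 for astaxanthin. A prior variance with a robust trend gave 1881, 2656 and 3865 against SED, 351 for the interaction, 434 for exercise and 943 for astaxanthin. Without the dye term AX and AX+ME against SED had 702 and 1085. A threshold of 2-fold in both dyes gave 266, 268 and 354 against SED, 58 and 40 for AX+ME against ME and AX and 332 for the interaction, and a threshold of 1.2-fold gave 3730, 4093, 4932, 1442, 1252 and 4007. Quantile normalization within each dye moved the split at 1.5-fold for AX+ME against ME from 256 higher and 35 lower to 134 and 72, and for AX+ME against AX from 171 and 66 to 140 and 86.

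With array columns from 70 alone limma called 0 genes for ME and 0 for AX and 3 for AX+ME against SED, and 0 for the interaction, exercise and astaxanthin (3562, 4072, 5406, 2016, 3411 and 4652 at an unadjusted p under 0.05). Lists for exercise rose to 3, and counts at 1.5-fold in both dyes were 116, 99 and 311 against SED and 306 for the interaction. With quantile normalization as well the counts were 0, 3 (Trh, Dtl and a transcript without a symbol) and 5 (Olfr1232, Olfr910, Krt80 and 2 without a symbol) against SED and 0 for the interaction, exercise and astaxanthin (unadjusted 3734, 4149, 5582, 2092, 3640 and 4455), with 3 lists for exercise. At 1.5-fold in both dyes they were then 106, 99 and 294 against SED, 139 for AX+ME against ME and 265 for the interaction. These fits leave out the dim area and test fewer genes. They use another probe for several genes, which turned Vash1 to 0.16, 0.18 and 0.15 in ME, AX and AX+ME against SED (0.17, 0.16 and 0.14 with quantile normalization). For astaxanthin Bach2 turned to -0.93 (-1.06), Tmem163 to 0.10 (0.014) and Oprl1 to 0.19 (0.14). With the same probe but only its spot from column 70 on, Lepr turned to 0.023 (0.00986) in ME against SED and to 0.023 (0.017) for exercise, and the mitochondrial list for astaxanthin to 0.00463 with quantile normalization. Vash1 also turned with another probe where saturated probes were left out (0.11, 0.12 and 0.088) and with quantile normalization (0.028, 0.23 and 0.046), which turned Lep in AX against SED to -0.068.

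With an estimated correlation 0 lists passed camera in every comparison (0 for ME, 0 for AX+ME against SED, 0 against ME, 0 against AX, 0 for the interaction, 0 for exercise and 0 for astaxanthin; unadjusted p under 0.05 for 2, 1, 5, 5, 2, 1 and 3), while fry, which tests a list alone, passed 8, 10 and 6 against SED, 2 for AX+ME against AX, 5 for the interaction, 6 for exercise and 11 for astaxanthin. Camera with an estimated correlation has at most the model's 3 residual degrees of freedom, so not passing it does not show that a list is unchanged. Fits of only the 4 samples compared called 0, 0 and 0 against SED (unadjusted 3538, 3679 and 4275), with a single residual degree of freedom. Models with only the 2 levels called 0 for exercise and 0 for astaxanthin (unadjusted 1813 and 3871). Without the SED samples AX+ME against ME and against AX kept 0 and 0 (unadjusted 3510 and 2532).

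Leaving out each sample in turn, with the lone sample assumed to vary like the other groups, gave 0 to 4725 genes for ME, 0 to 5037 for AX and 0 to 5387 for AX+ME against SED, 0 to 0 for AX+ME against ME, 0 to 11 against AX, 0 to 2822 for the interaction, 0 to 2974 for exercise and 0 to 3618 for astaxanthin. The highest of those against SED, of the interaction and of the main effects came without SED replicate 1. Without SED replicate 2 they were 1331, 1527, 2087, 637, 864 and 930. Without ME replicate 1 or 2, AX replicate 1 or 2, or AX+ME replicate 1 or 2 every count was 0, except 7 for AX against SED and 11 for AX+ME against AX without AX replicate 1; unadjusted p-values under 0.05 then numbered 3118 to 5616, 4123 to 6453 and 5475 to 7254 against SED. Calls were also lost in comparisons that do not use the sample left out, and these fits have fewer residual degrees of freedom. The cause was not tested. Lists past camera ranged from 1 to 3 for ME against SED (1 without SED replicate 1), 0 to 0 for AX, 1 to 3 for AX+ME (3 without AX+ME replicate 2), 4 to 11 for AX+ME against ME (11 without AX+ME replicate 2), 4 to 8 against AX (4 without AX replicate 1), 0 to 2 for the interaction (0 without SED replicate 1, 1 without SED replicate 2), 1 to 1 for exercise and 3 to 6 for astaxanthin. Lep ranged from -0.36 (without SED replicate 2) to 0.55 (without SED replicate 1) in ME and from -0.38 to 0.53, with the same samples left out, in AX against SED. It turned to -0.14 in ME without ME replicate 2 and to -0.024 in AX without AX replicate 2.

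No paired analysis was possible because the replicate number is the dye, which the model already holds as a term, and no label ties samples of different groups together. Signal over background limits the genes near the floor: Lep was well above background on both arrays of AX+ME and on neither array of SED.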

Other observations

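All tests here were chosen before their results were seen, and the list values are given without explanation.

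For each main effect, every other split of the 8 samples into 4 and 4 was fitted with a term for the split and a term for dye. Of 35 splits, 1 follows the dye and could not be fitted. In this model the real split called 0 genes for exercise and 0 for astaxanthin in limma (1813 and 3871 at an unadjusted p under 0.05), so all 34 of 34 splits called at least as many by construction, and the test says nothing about chance. The highest other split called 21 genes, and 2 splits called any.

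The lists below did not pass camera over all columns in any comparison above. In AX+ME against SED their medians were 0.06 for neurotrophic and growth factors, -0.21 for antioxidant and Nrf2 targets, -0.09 for inflammation, -0.05 for carotenoid and retinoid handling, -0.07 for heat shock and ER stress, -0.05 for the circadian clock, -0.13 for glucose, lactate and glycogen use, -0.10 for PPAR and lipid handling and -0.10 for cytosolic ribosomal proteins. Among cell types and tissues they were -0.16 for CA pyramidal cells, -0.01 for GABAergic interneurons, -0.05 for astrocytes, -0.09 for oligodendrocytes, 0.06 for oligodendrocyte precursors, -0.13 for microglia, -0.07 for endothelium, 0.03 for thalamus and habenula, -0.09 for hypothalamus, -0.19 for neocortex, -0.01 for neutrophils and -0.21 for adipose tissue. The median and the test pointed opposite ways, without passing, for carotenoid and retinoid handling, the circadian clock, GABAergic interneurons, hypothalamus and neutrophils. Per1, Fabp4 and Lpl each stand in a pair of lists; no choroid plexus, pituitary or meningeal gene does.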
